A study of Mus musculus with 5 samples.

How the data were processed

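RNA was measured by sequencing in kidneys of C57BL/6J mice, an inbred laboratory strain, from 3 vehicle samples and 2 samples treated with DMXAA. DMXAA is a small molecule that activates mouse STING, the adaptor through which cytosolic DNA sensing induces interferon. Per the labels' protocols the males were 8 weeks old, injections were intraperitoneal at 10 mg/kg once a day for 3 days, and tissue was taken on day 3. RNA was extracted with Trizol. The labels' protocols name both an Illumina TruSeq RNA kit and a NEBNext Ultra RNA kit for library construction and do not say which was used for which sample, so no library batch could be tested.

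The authors deposited 1 table of raw read counts, whole numbers per Ensembl gene ID, with 1 column per sample. Per the submitters' processing notes, HISAT2, featureCounts, Subread, DESeq2 1.16.1 and the mouse build mm10 were used. The role of each tool, the gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of a gene and of an overlapping or antisense gene therefore cannot be told apart, and genes with near-identical copies (haemoglobin, immunoglobulin, class I histocompatibility, guanylate-binding protein, serum amyloid A, ribosomal protein and mitochondrial genes) have uncertain levels. Columns were assigned by their names, with CO1 to CO3 read as control replicates 1 to 3 and XA1 and XA2 as DMXAA replicates 1 and 2. No sample column was left unassigned.

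Total counts were 17667490, 18552912 and 17712843 in the vehicle libraries and 18176586 and 20264228 in the DMXAA libraries. The table listed 54532 gene IDs, of which 28037 had a count in any library. GENCODE mouse release M21, on the same genome assembly as mm10, gave symbols for 99.8% of the IDs, and its coordinates, transcript lengths and GC contents were used. At these depths a count of 0 allows up to 0.148 to 0.170 CPM, taking 3 counts as the limit, which covers counting error only. No pair of libraries matched within sampling noise (chi-square per degree of freedom 7.95 to 42.4), so all 5 were kept as separate samples. The labels number the samples as replicates but do not say that each came from a separate mouse, so p-values of single genes measure the spread between these samples.

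The test was edgeR 4.0.16's quasi-likelihood F test in R 4.3.3, two-sided, with TMM scaling, the default expression filter and group as the only term. The filter kept 16226 genes, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. Levels are in CPM, TMM-normalised and scaled to library size, computed from the deposited counts. Log2 fold changes are DMXAA over vehicle with their standard errors (SE). The biological coefficient of variation was 19.0%.

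A set of 32 gene lists (pathways, kidney cell types, immune cells, neighbouring tissues, and genes that respond to handling or time of day) was fixed before the data were examined. Each list was tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 32 lists. Camera asks whether a list moved relative to all other genes. At that preset the genes of a list count as nearly independent, so camera's p also depends on the number of genes. The tests were repeated with the correlation estimated from the data and with fry. The estimated correlation was 0.597 for the interferon-stimulated antiviral genes and 0.948 for the interferon-induced GTPases. The text names up to 4 members of each list with the smallest unadjusted p, the 8 largest called changes in each direction (none were called), and Tmem173 (the symbol of Sting1 in this annotation), Cgas, Nphs1, Ifnb1, Havcr1 and Lcn2, although not every gene under this rule is reported. Other genes were named after their values were seen, and are marked so.

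The alternatives chosen beforehand were DESeq2 1.42.0, relative log expression (RLE) size factors, no expression filter, a filter of at least 1 CPM in 2 samples, robust empirical Bayes, removal of the 20 most abundant and the mitochondrial genes, the replicate number as a block, and leaving out each library in turn. A bias-adjusted quasi-likelihood fit and a correction for transcript length and GC content were added after the data were seen. The procedure was tested on simulated counts for the same 16226 genes, 3 libraries against 2. There, edgeR called 61 of 100 genes changed 2-fold, 99 of 100 changed 4-fold and 14 unchanged genes, while DESeq2 called 72, 98 and 30. These changed genes were drawn from genes outside the lists with an average log2 CPM above 1, so the detection of rarer genes was not measured. A list shifted by 0.5 on the log2 scale was recovered, and 1 other list was called with it.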

Results

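Kidney transcript levels were compared between mice given DMXAA, an activator of mouse STING, and mice given vehicle, to ask which genes and gene groups differed after 3 daily injections. There were 3 vehicle and 2 DMXAA libraries, with 17667490 to 20264228 counts each. Levels are normalised CPM, given as mean ± SD over the 3 vehicle libraries (n = 3) and the 2 DMXAA libraries (n = 2).

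Interferon-stimulated antiviral genes had a median log2 fold change of 0.65 in the DMXAA kidneys (camera adjusted p = 1.19e-24; adjusted p = 0.339 with an estimated correlation). The radical-SAM antiviral enzyme Rsad2 was at 40.2 ± 2.13 CPM in vehicle and 63.4 ± 5.53 CPM in DMXAA, and Ifi44 at 15.8 ± 0.813 and 30.7 ± 6.46 CPM. Most complement, proximal tubule and cell cycle genes also had higher estimates, while most immediate-early, haemoglobin, B cell and mitochondrially encoded transcripts had lower ones. With the default expression filter no single gene passed edgeR's test after adjustment over all genes, and every list call below was lost when the inter-gene correlation was estimated from the data.

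The quasi-likelihood test in edgeR called 0 of 16226 genes, with a smallest adjusted p of 0.535. Without an expression filter it called 34 genes, among them Rsad2, Ifi44, Oas1a, Irf7, C1ra, Saa1, Saa3, Slc5a12, Ppara (all higher), mt-Atp6, Hba-a1 and Hbb-bs (all lower). At an unadjusted p below 0.05 it counted 1062 genes, 632 higher and 430 lower, against 811.3 expected by chance. In 26.0% of tested genes both DMXAA libraries lay beyond all 3 vehicle libraries, against 20% by chance. DESeq2 called 54 genes, 46 higher and 8 lower, 15 of them by at least 2-fold. All 54 had groups that did not overlap and an unadjusted p below 0.05 in edgeR. The DESeq2 count depended on single libraries: it was 133, 179 and 34 without vehicle library 1, 2 and 3, and 27 and 4 without DMXAA library 1 and 2. Without vehicle library 1, edgeR called 2 genes, the matricellular gene Ccn1 (lower, 55.7 ± 23.6 and 23.3 ± 1.28 CPM over all libraries) and C030005K06Rik (higher), the latter named after its values were seen.

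The libraries of a group were not alike. The DMXAA pair correlated at 0.987 (Pearson, log2 CPM across genes, which are not independent), and all other pairs lay between 0.959 and 0.982. The first principal component held 44.9% of the variance and ran from vehicle library 1 (-56.8) to vehicle library 2 (40.1), while the second, with 25.5%, placed both DMXAA libraries (19.6 and 35.3) above all vehicle libraries (-9.1 to -32.8). Vehicle library 1 was rich in adipose and urothelial transcripts, with 36.8 CPM of the adipokine Adipoq against 0 to 0.89 CPM in the other libraries and 27.2 CPM of Krt19 against 0.85 to 3.05 CPM. Vehicle library 2 was rich in interferon-induced GTPase transcripts. Log2 fold changes correlated with transcript length (Spearman 0.27 over 10425 genes with an average log2 CPM above 3, which are not independent) and with GC content (-0.13). The length trend was steepest in vehicle library 2, from a median of 0.19 at up to 1000 bases to -0.15 above 8000. It ran from -0.08 to 0.03 in vehicle library 1 and from 0.02 to 0.0037 in vehicle library 3. In DMXAA it ran from -0.08 to 0.06 and from -0.05 to 0.07. Mitochondrially encoded genes took 8.98 to 9.96% of the counts in vehicle and 8.70 and 7.80% in DMXAA.

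**Figure D1:**
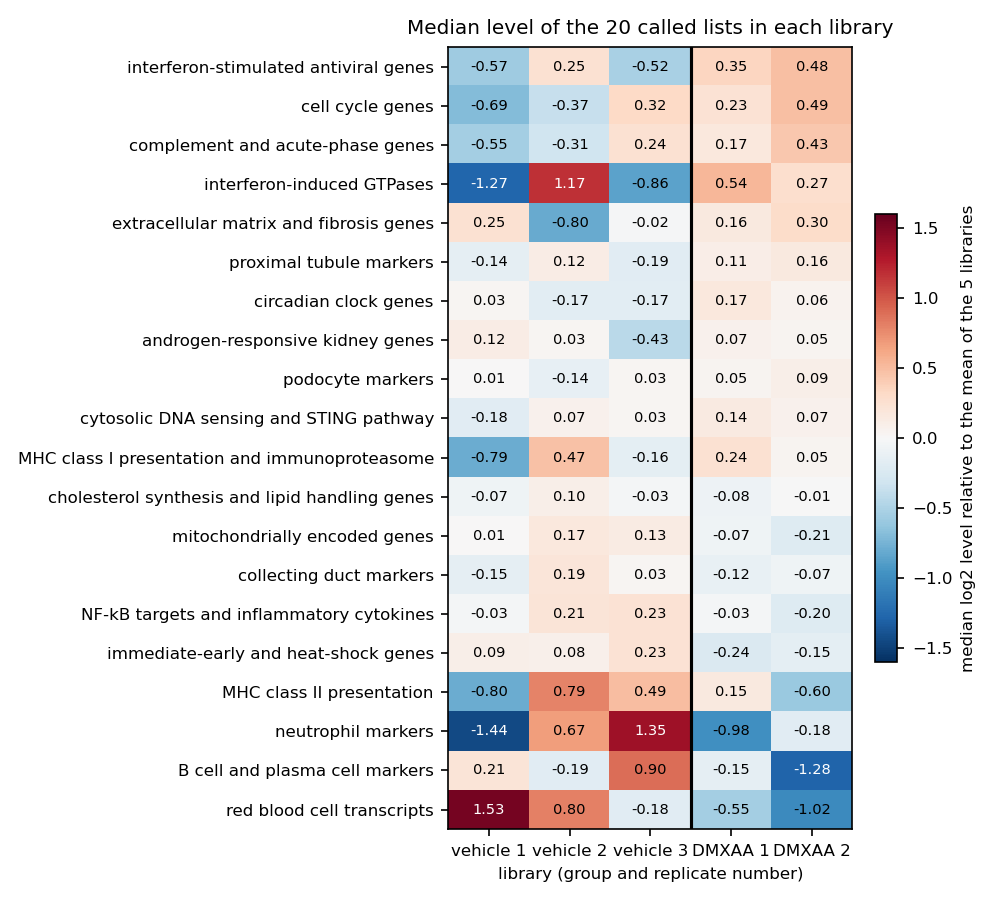
Median log2 level of the 20 lists called by camera at the preset correlation, in each of the 5 libraries, relative to the mean of the 5 libraries (colour and printed value). Antiviral genes were at 0.35 and 0.48 in the DMXAA libraries and -0.57, 0.25 and -0.52 in the vehicle libraries, and the GTPases peaked in vehicle library 2 at 1.17.

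Of the 38 measured interferon-stimulated antiviral genes, 36 had estimates above 0, 17 of these at an unadjusted p below 0.05, and 22 lay above all vehicle libraries in both DMXAA libraries, where chance gives 20% of genes for both directions together. The median log2 fold change was 0.65 (camera adjusted p = 1.19e-24; adjusted p = 0.339 with an estimated correlation). Adjusted over the list alone, 3 genes were called by edgeR, all higher: Rsad2 (log2 fold change 0.66, SE 0.10), Ifi44 (0.96, SE 0.15) and the oligoadenylate synthetase Oas1a (1.30, SE 0.26; 5.01 ± 1.38 and 12.3 ± 2.61 CPM). DESeq2 also called these 3, at adjusted p of 0.0016, 0.0014 and 0.0155. The antiviral ubiquitin ligase gene Trim30a was at 10.7 ± 1.66 and 16.7 ± 0.36 CPM. Named after its values were seen, Irf7, the regulator of interferon-alpha genes, had the largest estimate of the list (log2 fold change 1.99, SE 0.54), with 48.8, 193 and 68.4 CPM in vehicle and 343 and 478 CPM in DMXAA. The adjusted p of Irf7 was 0.724 in edgeR, 0.041 in edgeR without an expression filter and 0.637 in DESeq2. On mm10, Rsad2 (ENSMUSG00000020641) spans chromosome 12 from 26442746 to 26456452, Ifi44 (ENSMUSG00000028037) chromosome 3 from 151730922 to 151749960, and Oas1a (ENSMUSG00000052776) chromosome 5 from 120896256 to 120907521. Leaving out any 1 library kept the list call, with medians of 0.54 to 0.89. Ifnb1, the interferon-beta gene, had 0 counts in all 5 libraries, which allows up to 0.148 to 0.170 CPM in each.

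Interferon-induced GTPases, which act against intracellular pathogens, had a median of 0.42 over 17 genes (camera adjusted p = 5.04e-04; adjusted p = 0.625 with an estimated correlation), with 11 estimates above 0, 1 gene at an unadjusted p below 0.05 and 0 genes called by edgeR over the list alone. Gbp9 was at 17.3 ± 6.16 and 33.2 ± 1.48 CPM and Gbp5 at 9 ± 7.08 and 17.4 ± 1.2 CPM. The value depended on which vehicle libraries were kept. In vehicle library 2 Iigp1, named after its values were seen, reached 717 CPM against 35.6 and 50.8 CPM in vehicle libraries 1 and 3 and 135 and 106 CPM in DMXAA. Without vehicle library 2 the median was 1.41 (camera adjusted p = 2.7e-75), without library 1 it was -0.07 (0.265), without library 3 it was 0.07 (0.0664), and without DMXAA library 1 it was 0.17 (0.0135).

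Class I antigen presentation and immunoproteasome genes had a median of 0.10 over 20 genes, with 11 estimates above 0 (camera adjusted p = 2.03e-04; adjusted p = 0.625 with an estimated correlation). H2-Q6 was at 101 ± 16.5 and 166 ± 5.80 CPM and was the only gene called over the list alone. DESeq2 called it (adjusted p = 0.0103) and H2-D1 (912 ± 282 and 1815 ± 114 CPM, adjusted p = 0.0313), while H2-K1 was at 1417 ± 541 and 2590 ± 21.2 CPM. Reads shared within this family make these levels uncertain. Without vehicle library 2 the list median was 0.66, without vehicle library 1 it was -0.03 (camera adjusted p = 0.115), without DMXAA library 1 it was -0.02 (0.0064, camera's direction still up) and without DMXAA library 2 it was 0.25. Class II presentation genes had a median of -0.54, with 10 of 11 estimates below 0, 1 gene at an unadjusted p below 0.05 and 0 called over the list alone (camera adjusted p = 0.0114; adjusted p = 0.625 with an estimated correlation). H2-Eb1 was at 238 ± 104 and 132 ± 57.8 CPM and H2-Ob at 2.28 ± 0.635 and 0.785 ± 0.617 CPM. The class II call was lost without vehicle library 2 (-0.09, adjusted p = 0.455), vehicle library 3 (-0.40, 0.355) or DMXAA library 2 (-0.23, 0.584), and the median was -0.81 and -0.92 without vehicle library 1 and DMXAA library 1.

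The cytosolic DNA sensing and STING pathway list had a median of 0.11, with 16 of 21 estimates above 0, 4 genes at an unadjusted p below 0.05 and 0 genes called over the list alone (camera adjusted p = 0.0157; adjusted p = 0.599 with an estimated correlation). Its call was lost without vehicle library 1 (0.03, adjusted p = 0.254) or DMXAA library 1 (0.09, 0.0656), and its median was 0.25 without DMXAA library 2 and 0.07 after correction for length and GC content. Tmem173, which encodes STING, the target of DMXAA in mice, was at 5.61 ± 0.988 and 4.35 ± 0.67 CPM, and Cgas, the DNA sensor upstream of it, at 1.09 ± 0.20 and 1.33 ± 0.40 CPM. The groups overlapped for both genes, and the log2 fold change of Cgas, 0.28, was -0.05 without DMXAA library 1. The DNA-sensor family gene Ifi204 was at 4.83 ± 0.72 and 9.74 ± 2.62 CPM, Ifi203 at 14.9 ± 1.96 and 20.7 ± 2.82 CPM, and the transcription factor Irf3 at 50.1 ± 3.43 and 41.2 ± 0.81 CPM.

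Complement and acute-phase genes had a median of 0.42, with 17 of 23 estimates above 0 (camera adjusted p = 8.23e-09; adjusted p = 0.339 with an estimated correlation). Over the list alone edgeR called 4 genes, all higher. C1ra, a protease of the classical complement pathway (ENSMUSG00000055172, chromosome 6 from 124512405 to 124523443), was at 26.8 ± 3.34 and 53.4 ± 3.30 CPM, a log2 fold change of 0.99 (SE 0.13), and Cfb, complement factor B, was at 17.7 ± 0.59 and 27.5 ± 1.51 CPM. DESeq2 called both over all genes (adjusted p = 1.12e-05 and 0.0171). The serum amyloid A genes differed widely between the DMXAA libraries: Saa1 was at 0, 0.28 and 0 CPM in vehicle and 9.49 and 123 CPM in DMXAA, and Saa3 at 0.16, 0.34 and 0.61 CPM in vehicle and 1.28 and 27.1 CPM in DMXAA. Lcn2, an acute-phase and tubular injury gene, was at 10.8 ± 5.63 and 22.5 ± 22.7 CPM, a log2 fold change of 1.06 that was -0.74 without DMXAA library 2. In the other direction, Cfd and Hp, named after their values were seen, were high only in vehicle library 1 (284 and 27.3 CPM), the library rich in adipose transcripts. The list was called without each library in turn, with a median of 0.24 without DMXAA library 2. Its median level overlapped between the groups, at 0.24 in vehicle library 3 and 0.17 in DMXAA library 1 relative to the mean of all libraries.

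**Figure D2:**
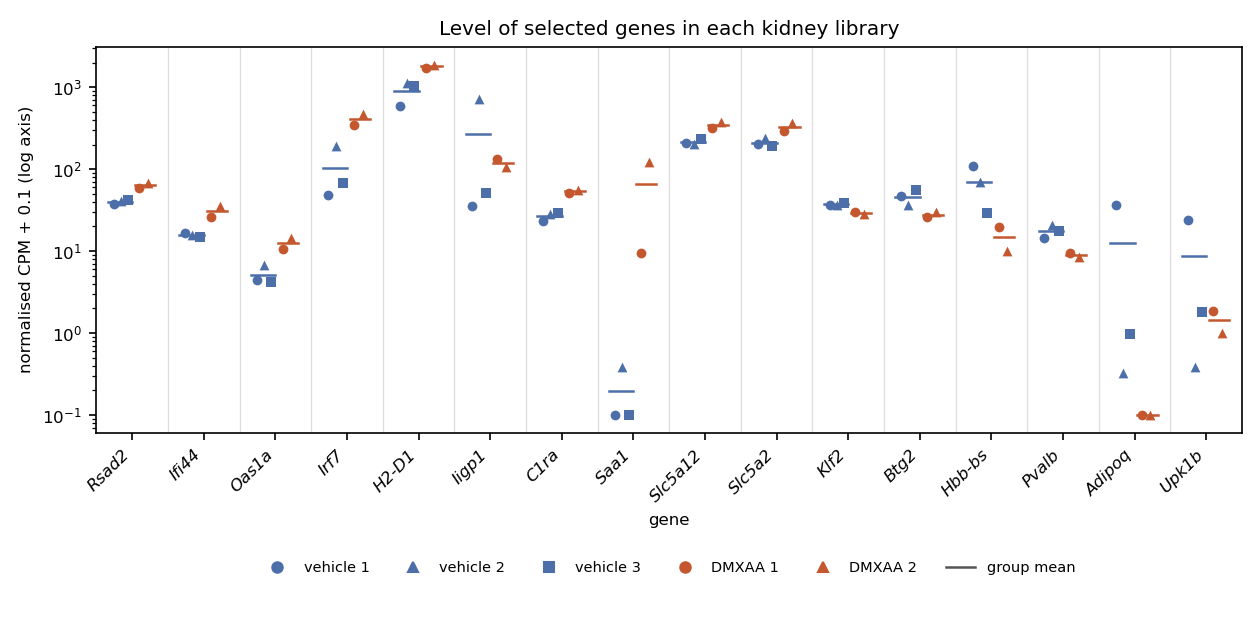
Normalised CPM plus 0.1, on a log axis, of 16 genes in each of the 5 libraries, with vehicle in blue, DMXAA in orange, the symbol shape giving the replicate number and lines giving group means. Rsad2, Ifi44, Oas1a and C1ra were higher in both DMXAA libraries than in all vehicle libraries, Saa1 spanned 9.49 to 123 CPM within DMXAA, and Iigp1, Adipoq and Upk1b each peaked in 1 vehicle library.

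NF-kB targets and cytokines had a median of -0.26, with 18 of 22 estimates below 0, 3 genes at an unadjusted p below 0.05 and 0 called over the list alone (camera adjusted p = 0.00194; adjusted p = 0.421 with an estimated correlation). The lymphotoxin gene Ltb was at 1.84 ± 0.238 and 0.77 ± 0.245 CPM, and Tnip1, an inhibitor of NF-kB signalling, at 38.8 ± 6.78 and 27.7 ± 0.40 CPM. That call was lost without DMXAA library 2 (-0.17, adjusted p = 0.0755). The chemokine list was not called (median -0.07 and mean -0.15 over 13 genes, although camera's direction was up, adjusted p = 0.638). Its median ran from -0.25 without DMXAA library 1 to 0.19 without vehicle library 2. It was 0.06 without DMXAA library 2 and 0.03 after correction for length and GC content. Over that list alone, Ccl5, a T cell attractant, was called higher (3.70 ± 0.59 and 8.58 ± 2.56 CPM), while the neutrophil attractant Cxcl1 was at 3.71 ± 3.00 and 0.94 ± 0.22 CPM.

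Among kidney cell types, proximal tubule markers had a median of 0.23, with 24 of 30 estimates above 0 (camera adjusted p = 3.55e-08; adjusted p = 0.421 with an estimated correlation). Genes called higher over the list alone included Slc5a12, a lactate transporter (215 ± 14.4 and 351 ± 41.6 CPM, log2 fold change 0.70, SE 0.12), and Slc5a2, the glucose transporter SGLT2 (210 ± 23.4 and 327 ± 50.7 CPM), and none was called lower. DESeq2 called Slc5a12 and Slc5a2 over all genes (adjusted p = 1.76e-04 and 0.0218). This list was called without each library in turn, with medians of 0.16 to 0.34. Its median level overlapped between the groups, at 0.12 in vehicle library 2 and 0.11 in DMXAA library 1 relative to the mean of all libraries.

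Podocyte markers had a median of 0.12, with 14 of 23 estimates above 0, 4 genes at an unadjusted p below 0.05 and 0 genes called over the list alone (camera adjusted p = 0.0292; adjusted p = 0.625 with an estimated correlation). The slit diaphragm gene Nphs1 was at 21.1 ± 1.45 and 26.3 ± 1.09 CPM. The call was lost without vehicle library 2 (0.0082, adjusted p = 0.429), without DMXAA library 2 (0.07, 0.285) and after correction for length and GC content (0.06, 0.109), and the median was 0.23 without vehicle library 3. Collecting duct markers had a median of -0.22, with 17 of 19 estimates below 0, 0 genes at an unadjusted p below 0.05 and 0 called over the list alone (camera adjusted p = 0.00449; adjusted p = 0.339 with an estimated correlation). The water channel gene Aqp4 was at 103 ± 60.5 and 61.7 ± 6.25 CPM. Its groups overlapped, with 171, 55.6 and 81.5 CPM in the vehicle libraries and 66.1 and 57.3 CPM in the DMXAA libraries. Summed inner medulla markers (9 genes, of which 6 are in another list) were at 1880 CPM in vehicle library 1 and 555 to 759 CPM in the other 4 libraries. The median level of the collecting duct list was nevertheless lowest in vehicle library 1 (-0.15 relative to the mean of all libraries). Its call stayed without that library (-0.19, camera adjusted p = 3e-04). The collecting duct call was lost without vehicle library 2 (-0.11, adjusted p = 0.0532) or DMXAA library 1 (-0.24).

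Loop of Henle and distal tubule markers were not called (median 0.09, camera adjusted p = 0.42), but Pvalb, a calcium-binding protein of the distal convoluted tubule, was called lower over that list alone and by DESeq2 (17.6 ± 3.30 and 8.9 ± 0.835 CPM, adjusted p = 0.0171 in DESeq2). Without vehicle library 3 the list was called (0.11, camera adjusted p = 0.0256). Endothelial markers (median 0.13, camera adjusted p = 0.0727) and mesangial, pericyte and fibroblast markers (median 0.08, mean -0.03, adjusted p = 0.235) were not called. After correction for length and GC content the endothelial list was called higher (0.14, adjusted p = 0.0429). Without vehicle library 1 both were called higher (endothelial 0.21, adjusted p = 3.07e-04; mesangial 0.32, 1.61e-04), and the endothelial list also without vehicle library 3 (0.15, 0.0141). Without vehicle library 2 both medians turned below 0 (endothelial -0.0029, mesangial -0.07). Endothelial Tie1 was at 42.7 ± 7.29 and 58.4 ± 5.88 CPM and renin (Ren1) at 61.3 ± 16.5 and 110 ± 52.1 CPM. Extracellular matrix and fibrosis genes had a median of 0.38, with 18 of 26 estimates above 0, 12 genes above all vehicle libraries (20% by chance for both directions together), 5 at an unadjusted p below 0.05 and 0 called over the list alone (camera adjusted p = 1.9e-06; adjusted p = 0.599 with an estimated correlation). Loxl1, a collagen cross-linking enzyme, was at 12.6 ± 3.19 and 22.4 ± 0.76 CPM, and the basement membrane collagen Col4a1 at 242 ± 27.8 and 335 ± 49.7 CPM. The matrix call was lost without vehicle library 2 (0.28, adjusted p = 0.0532), and the median was 0.20 without DMXAA library 2. Tubular injury markers were not called (median -0.02, adjusted p = 0.638) except without vehicle library 1 (-0.0075, 0.0141), their median was 0.08 without vehicle library 2 and 0.03 after correction for length and GC content, and Havcr1 (KIM-1) was at 3.72 ± 1.42 and 4.85 ± 1.52 CPM.

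Blood and immune cell transcripts moved unevenly. Red blood cell transcripts had a median of -1.83, with 7 of 9 estimates below 0 (camera adjusted p = 1.32e-06; adjusted p = 0.339 with an estimated correlation), and 5 were called lower over the list alone. Hbb-bs was at 69.1 ± 39.5 and 14.9 ± 6.86 CPM and Hba-a1 at 82.3 ± 50.8 and 20.6 ± 7.11 CPM. B cell and plasma cell markers had a median of -0.99, with 12 of 14 estimates below 0 (camera adjusted p = 2.46e-07; adjusted p = 0.339 with an estimated correlation). Ighd was called lower over the list alone and was at 0.85 ± 0.09 and 0.02 ± 0.04 CPM, with 1 count in the DMXAA libraries together. The B cell median was -0.52, -0.60 and -0.09 without vehicle library 1, 2 and 3, and -1.53 without DMXAA library 1, and it was -0.40 with the 1 CPM filter (camera adjusted p = 0.00126). The median level of the B cell list overlapped between the groups, at -0.19 in vehicle library 2 and -0.15 in DMXAA library 1. Neutrophil markers had a median of -0.86, with 6 of 7 estimates below 0, 0 genes at an unadjusted p below 0.05 and 0 called over the list alone (camera adjusted p = 0.0226; adjusted p = 0.625 with an estimated correlation). S100a9 was at 1.14, 8.76 and 23.1 CPM in vehicle and 1.28 and 2.34 CPM in DMXAA. The neutrophil call was lost without vehicle library 2 (-0.82, adjusted p = 0.321), vehicle library 3 (-0.33, 0.618) or DMXAA library 1 (-1.26, 0.0647), and the median was -1.34 and -2.05 without vehicle library 1 and DMXAA library 2 and -1.54 with the 1 CPM filter.

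Macrophage and monocyte markers were not called (median 0.04, camera adjusted p = 0.158), with Mpeg1 at 41.0 ± 5.56 and 54.5 ± 5.11 CPM. Without vehicle library 3 the macrophage list was called higher (0.25, adjusted p = 0.00182), and without DMXAA library 1 its median was -0.0097. T and NK cell markers were not called either (median -0.22, camera adjusted p = 0.638). Within that list the cytotoxic granule protease Gzma was called higher over the list alone and by DESeq2 (2.05 ± 0.39 and 5.83 ± 0.48 CPM, adjusted p = 0.00779 in DESeq2), Gzmb was at 3.47 ± 0.815 and 6.51 ± 2.88 CPM, and the T cell receptor gene Trbc2 at 1.98 ± 0.79 and 0.91 ± 0.52 CPM. The list median was -0.81 without DMXAA library 1 (adjusted p = 1.1e-05) and 0.26 without DMXAA library 2 (adjusted p = 7.99e-04), so its direction depended on which DMXAA library was kept. The list of adrenal, adipose and pancreas transcripts was not called (median -0.58 over 6 genes, adjusted p = 0.638), and its median was 0.52 without vehicle library 1 (adjusted p = 0.0144), 0.08 without vehicle library 3 and -7.39 without DMXAA library 2 (0.0105).

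Cell cycle genes had a median of 0.56, with 25 of 30 estimates above 0, 6 genes at an unadjusted p below 0.05 and 0 called over the list alone (camera adjusted p = 9.37e-09; adjusted p = 0.559 with an estimated correlation). The DNA replication gene Mcm6 was at 32.5 ± 6.12 and 49.0 ± 4.34 CPM and the cyclin gene Ccnb2 at 2.15 ± 1.1 and 5.44 ± 0.40 CPM. The list was called without each library in turn, with a median of 0.26 without vehicle library 1 and 0.97 without vehicle library 3. Its median level overlapped between the groups, at 0.32 in vehicle library 3 and 0.23 in DMXAA library 1 relative to the mean of all libraries. Cell death genes were not called (median 0.04, camera adjusted p = 0.638) except without vehicle library 2 (0.13, 0.021), and their median was -0.03 without DMXAA library 1. In that list the pro-apoptotic gene Bbc3 was at 4.38 ± 1.2 and 2.18 ± 0.02 CPM and Mlkl, the effector of necroptosis, at 3.23 ± 0.459 and 5.24 ± 0.745 CPM.

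In metabolism, all 15 measured mitochondrially encoded genes had estimates below 0, with a median of -0.21 (camera adjusted p = 1.67e-07; adjusted p = 0.339 with an estimated correlation). The ATP synthase subunit gene mt-Atp6 was called lower over the list alone and by DESeq2 (196 ± 67.2 and 74.2 ± 8.55 CPM, adjusted p = 3.69e-04 in DESeq2). The median was -0.33 without vehicle library 1, -0.33 without DMXAA library 1 and -0.125 after correction for length and GC content (camera adjusted p = 8.95e-04). Nuclear-encoded oxidative phosphorylation genes were not called (median -0.03, adjusted p = 0.45) except without vehicle library 1 (-0.07, 0.0141), and their median was 0.06 without vehicle library 2, 0.06 without DMXAA library 1 and 0.04 after correction for length and GC content, with Ndufa1 at 108 ± 8.51 and 80.1 ± 4.33 CPM. Cholesterol and lipid handling genes had a median of -0.13, with 17 of 29 estimates below 0 (camera adjusted p = 0.0157; adjusted p = 0.484 with an estimated correlation). The desaturase gene Scd2 was called lower over the list alone and by DESeq2 (204 ± 10.5 and 139 ± 3.08 CPM, adjusted p = 2.87e-04 in DESeq2), and Srebf1, a regulator of lipid synthesis, was at 74.6 ± 10.6 and 50.8 ± 4.70 CPM. The lipid call was lost without vehicle library 2 (-0.02, adjusted p = 0.352) or DMXAA library 1 (-0.05, 0.112). Fatty acid oxidation genes were not called (median -0.07, adjusted p = 0.638) except without vehicle library 1 (-0.13, 0.00497), and their median was 0.04 without vehicle library 2, yet Ppara, a regulator of that pathway, was called higher over the list alone and by DESeq2 (50.9 ± 7.64 and 85.3 ± 5.70 CPM, adjusted p = 0.00548 in DESeq2). The unfolded protein and stress response list was not called (median -0.0033, mean -0.07, camera's direction up, adjusted p = 0.945). Its median was 0.05 without vehicle library 2, 0.05 without DMXAA library 1 and -0.12 without DMXAA library 2. Ddit3 was at 16.1 ± 2.53 and 23.6 ± 0.97 CPM.

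Immediate-early and heat-shock genes had a median of -0.44, with 23 of 28 estimates below 0 (camera adjusted p = 1.32e-09; adjusted p = 0.339 with an estimated correlation), and 7 were called lower over the list alone, among them Btg2 (46.3 ± 9.67 and 27.6 ± 2.76 CPM) and Klf2 (37.1 ± 1.14 and 29.4 ± 1.08 CPM). Circadian clock genes had a median of 0.21, with 13 of 19 estimates above 0 (camera adjusted p = 1.43e-04; adjusted p = 0.339 with an estimated correlation). Of these, 5 were called higher over the list alone, including the transcription factor gene Hlf (104 ± 8.33 and 136 ± 3.52 CPM), the period gene Per2 (27.4 ± 4.81 and 41.8 ± 5.01 CPM) and the clock output gene Usp2 (120 ± 6.08 and 172 ± 14.5 CPM). DESeq2 called Usp2 over all genes (adjusted p = 0.00733). Both lists were called without each library in turn, the clock list with a median of 0.13 without DMXAA library 1. The first list was chosen to track handling and RNA quality, and the clock list to track the time of harvest. Unequal handling or harvest time between the groups was not tested and cannot be told apart from an effect of DMXAA. Androgen-responsive kidney genes had a median of 0.16, with 13 of 19 estimates above 0 (camera adjusted p = 0.0425; adjusted p = 0.625 with an estimated correlation). Cyp4a12a, an arachidonic acid hydroxylase, was called higher over the list alone and by DESeq2 (31.6 ± 5 and 52.3 ± 6.41 CPM, adjusted p = 0.0299 in DESeq2). The androgen call was lost without vehicle library 3 (0.04, adjusted p = 0.737) or DMXAA library 1 (0.08, 0.333) and with the 1 CPM filter (0.15, 0.0548).

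**Figure D3:**
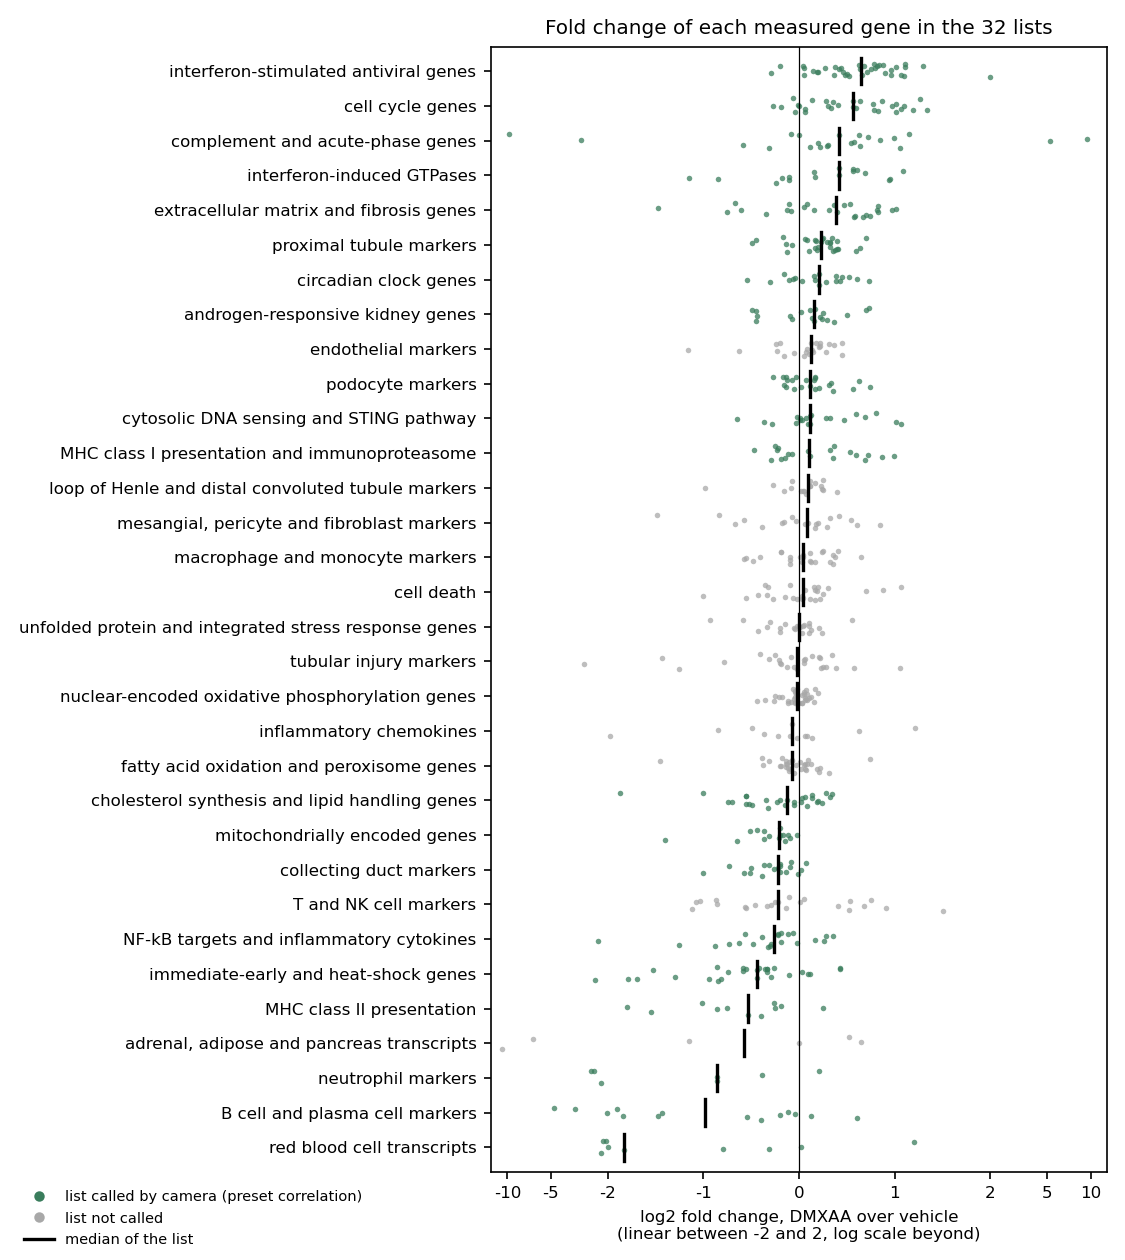
Log2 fold change, DMXAA over vehicle, of each measured gene in the 32 lists (1 point per gene, green where camera called the list at the preset correlation, grey where it did not, black bar at the median). The axis is linear between -2 and 2 and logarithmic beyond, and the medians run from -1.83 in red blood cell transcripts to 0.65 in antiviral genes.

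In the 9 called lists where edgeR called 0 genes over the list alone, DESeq2 called 0 over all genes as well. In total camera called 20 of the 32 lists at the preset correlation, 11 higher and 9 lower, and 9 of these 20 were called in all 5 fits that left out 1 library. Among those 9, the cell cycle, complement, proximal tubule and B cell lists overlapped between the groups in their median levels per library. With the correlation estimated from the data 0 lists were called (smallest adjusted p = 0.339). The rotation test fry called 0 lists in 1 direction (smallest adjusted p = 0.352) and 3 lists when changes in either direction counted, the mitochondrially encoded, circadian and lipid lists (adjusted p = 0.0455 for each).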

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

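The count of genes called by edgeR was 0, and it stayed at 0 with RLE size factors, the 1 CPM filter, robust empirical Bayes, removal of abundant and mitochondrial genes, and the 2 alternatives added after the data were seen (the bias-adjusted fit and the length and GC correction). DESeq2 called 54 genes, 46 higher, 8 lower and 15 by at least 2-fold. Without an expression filter edgeR called 34 genes, 29 higher, 5 lower and 21 by at least 2-fold, of which 26 were shared with DESeq2. Leaving out each library in turn gave 0 to 2 genes, 0 to 1 higher, 0 to 1 lower and 0 to 2 by at least 2-fold. With the replicate block there were 4 genes, 2 higher and 2 lower, all by at least 2-fold. These were Saa1 and Entpd4b (higher) and Hba-a1 and Hbb-bs (lower), Entpd4b named after its values were seen. Camera called 21 lists with the block, 17 of the 20 and 4 others. The lost calls were class II (-0.20, camera adjusted p = 0.169), neutrophil (-0.45, 0.272) and androgen (0.04, 0.791). The 4 others were loop of Henle (0.11, 0.0424), endothelial (0.18, 0.011), macrophage (0.31, 0.00238) and adrenal, adipose and pancreas (-0.38, 5.62e-06). The replicate numbers are not shown to pair the samples, and only 2 pairs exist. The deviations of same-numbered libraries from their group means correlated at 0.112 and 0.102. With 2 DMXAA libraries these deviations mirror each other, so the values are not independent and cannot decide the pairing. The count of lists called by camera was 20, and it fell to 0 with the correlation estimated from the data and to 0 with fry, was 15 to 23 when each library was left out, and 19 to 21 under the other alternatives. The T and NK cell median (-0.22) ranged from -0.81 to 0.26 and the adrenal, adipose and pancreas median (-0.58) from -7.39 to 0.52 over the leave-one-out fits, both changing sign. The medians of the GTPase, class I, chemokine, cell death, endothelial, mesangial, tubular injury, macrophage, oxidative phosphorylation, fatty acid oxidation and unfolded protein lists also changed sign in at least 1 of these fits. The cause was not tested for any of these differences. In simulated data edgeR called 61 of 100 genes changed 2-fold, all with an average log2 CPM above 1. Calls of rarer changed genes, or of single genes at smaller changes, were not counted. Genes were simulated independently, so false list calls among correlated genes were not measured. Depth limits the detection of rare transcripts, since a count of 0 allows up to 0.148 to 0.170 CPM.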

Other observations

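The test of whether a DMXAA-treated animal carried a vehicle label was written before its result was seen. The tests of adipose tissue, urothelium, scaling, leukocytes, length and GC content, an interferon-gamma-type response, liver tissue and other splits of the samples were chosen after the patterns were seen, as were the genes named here outside the rule.

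Several genes outside the lists were called by DESeq2 but not by edgeR with the default expression filter. Without the filter edgeR also called Cyp24a1, Ppp1r16b, Mgp, Ces1g, Ifitm3 and Fgf9. Cyp24a1, the enzyme that degrades active vitamin D, was at 41.7, 21.2 and 33.2 CPM in vehicle and 101 and 299 CPM in DMXAA (log2 fold change 2.64, SE 0.46, adjusted p = 0.0153 in DESeq2 and 0.547 in edgeR). The activating enzyme Cyp27b1 was at 3.38 ± 0.67 and 3.71 ± 1.09 CPM, and the vitamin D receptor Vdr at 246 ± 23.3 and 295 ± 3.72 CPM, with adjusted p of 0.926 and 0.741 in edgeR. Ppp1r16b, a regulatory subunit of protein phosphatase 1, had the smallest DESeq2 adjusted p (3.26e-06), at 60.6 ± 8.78 and 143 ± 29.8 CPM. Mgp, an inhibitor of calcification, was at 57.8 ± 6.97 and 111 ± 8.07 CPM (DESeq2 adjusted p = 3.58e-06).

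Further genes, apart from Gapdh, were named because DESeq2 called them. The ubiquitin ligase gene Trim25, which acts in RIG-I signalling, was at 105 ± 1.67 and 157 ± 5.15 CPM, and Ifitm3, which blocks virus entry, at 54.7 ± 1.70 and 85.0 ± 9.65 CPM (DESeq2 adjusted p = 2.06e-05 and 0.00184). The carboxylesterase gene Ces1g was at 2.32 ± 1.05 and 10.2 ± 0.97 CPM, the bile acid receptor gene Nr1h4 at 111 ± 11.1 and 167 ± 10.6 CPM and the transcription factor gene Foxo3 at 104 ± 4.42 and 151 ± 2.63 CPM, all called higher by DESeq2 (adjusted p = 1.76e-04, 0.00932 and 4.03e-04). Fgf9 was called lower, at 26.1 ± 2.51 and 14.4 ± 0.11 CPM (adjusted p = 0.0014). Gapdh, whose reads can be shared with many processed pseudogenes, was listed at 7.46, 217 and 5.05 CPM in vehicle and 8.10 and 7.86 CPM in DMXAA.

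Other splits of the 5 libraries into 3 and 2 gave results as large as the real one. The real split counted 1062 genes at an unadjusted p below 0.05, the highest other split counted 1660, and 3 of the 10 splits, counting the real one, reached the real count. The antiviral list's median was 0.65 in the real split and 0.95 in size in the highest other, and 2 of the 10 splits, counting the real one, were as large. The highest other split for both values set vehicle libraries 1 and 3 against vehicle library 2 and DMXAA. It called 7 genes where the real split called 0, and the cause was not tested. With 10 splits the share cannot go under 0.1, so they are too few for a test.

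Vehicle library 1 stood apart from the other 4. Adipose markers lay above the mean of the others by a median of 3.14 on the log2 scale (95% bootstrap interval 1.45 to 6.94, 10 genes, of which 7 exceed 1 CPM elsewhere and 5 are in another list), and urothelial markers by 4.47 (3.76 to 4.82, 13 genes, 7 and 1). Bootstrap intervals here and below are taken over genes, which are not independent, and do not measure the spread between samples. Among the abundant transcripts, Cfd was at 284 CPM, Fabp4 at 271, Car3 at 231 and Upk1b at 23.8, against at most 5.71, 55.1, 19.5 and 1.78 CPM in the other libraries. The median difference of that library over all 16226 genes was 0.0058. TMM scaling sets this value near 0, so it cannot by itself exclude a scaling fault. A scaling factor shifts all genes of a library alike, however, so it cannot set these markers apart from the other genes. Fat and renal pelvis carried into the sampled piece may therefore be part of what sets this library apart; no biological explanation was tested, since the design names none within the vehicle group.

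Interferon-induced GTPases stood above the 2 other vehicle libraries in vehicle library 2 by a median of 2.26 on the log2 scale (17 genes), with Tgtp1 at 266 CPM against 62.8 and 52.1 CPM in DMXAA. More leukocytes would raise their markers alike, but these lay lower than the GTPases by 2.44 (1.88 to 3.26, 69 markers), and after correction for length and GC content the GTPase difference was still 2.12 (1.79 to 3.00). These intervals cover the spread over genes, with an estimated correlation of 0.948 for the GTPases, and not the spread between samples. The GTPases exceeded the antiviral genes by 1.45 (0.78 to 2.30), but they were picked because they stood high in that library, so this leaves an interferon-gamma-type response untested, and Ifng itself had 0, 0 and 1 counts in vehicle and 1 and 0 in DMXAA. A treated animal under a vehicle label cannot be told apart: outside the interferon lists, vehicle library 2 lay at 0.553 of the way from the other vehicle libraries to DMXAA (0.499 to 0.679, 139 genes), but vehicle libraries 1 and 3, treated the same way, lay at 0.530 and 0.428, so the measure does not separate them. Inside the interferon lists vehicle library 2 lay at 1.02 (40 genes). The 139 genes leave out only listed genes, so some of them may still respond to interferon. An infection or an unequal handling of that animal is untested.

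Serum amyloid A transcripts were high in the DMXAA libraries and very unequal between them, with Saa2 at 0, 0 and 0 counts in vehicle and 2 and 287 in DMXAA, beside the Saa1 and Saa3 levels in the complement list. Liver tissue would bring its abundant transcripts, but liver markers had a median log2 fold change of -0.47 (-0.66 to -0.02, 8 genes) and Alb was at 3.14 ± 1.32 and 2.97 ± 0.04 CPM. More macrophages and neutrophils would raise their markers, but the median log2 fold change of these was 0.0189 (-0.19 to 0.12, 32 genes). Reads shared between Saa1 and Saa2 could move counts from one gene to the other but not create them in libraries where both were near 0. An acute-phase response of the kidney remains open and untested.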
